A study of Mus musculus with 4 samples.

How the data were processed

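RNA was sequenced from macrophages sorted from tumours of MycCaP cells and of MycCaP cells that overexpress BMP4, with 2 libraries per group. Per the labels' protocols, RNA was purified on silica columns, only RNA with an integrity number above 7 was used, polyadenylated RNA was selected with magnetic beads, and strand-specific libraries were read in pairs on an Illumina NextSeq instrument. The deposited values are whole-number counts of reads per gene, made by the authors with HTSeq per the submitters' processing notes, which also list STAR 2.6.0b, RSEM and Bowtie2 2.2.3 and the mouse build GRCm38 (mm10). The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and gene families with near-identical members such as Orm1 and Orm3, Ear2 and Rnase2a, and Ly6c2, are uncertain where reads could be split between copies.

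The files held 39179 gene identifiers, of which 37607 were given a symbol from a reference table and 37693 had coordinates in GENCODE M21 (GRCm38). Identifiers without a symbol took at most 0.227% of a library's counts. Summary lines that name no gene were left out of library sizes and tests. Reads outside annotated genes made up 3.98% and 3.37% of all counted reads in MycCaP replicates 1 and 2 and 6.01% and 6.03% in MycCaP-BMP4 replicates 1 and 2. Reads that aligned to several places made up 8.01% and 8.49% against 10.6% and 9.35%, and reads in overlapping genes 2.91% and 2.74% against 2.84% and 2.70%. Mitochondrial genes took 0.671% and 1.63% of the gene counts in MycCaP TAMs and 3.28% and 2.85% in MycCaP-BMP4 TAMs. Genes with at least 1 count numbered 18006 and 18208 against 18764 and 18665. The gene with most counts took 2.13% at most, which was Apoe in MycCaP replicate 1. Chi-square per degree of freedom between libraries was 43.2 in the MycCaP pair and 279 in the MycCaP-BMP4 pair, far above sampling noise, so no library was a copy of another.

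The samples were grouped by the cell line in their labels. Counts were filtered with filterByExpr for the 2 groups, which left 14075 genes, scaled with TMM factors (0.916 and 0.972 for the MycCaP libraries, 1.14 and 0.988 for the MycCaP-BMP4 libraries) and tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. Fold changes are MycCaP-BMP4 over MycCaP. The biological coefficient of variation was 0.363. CPM values use the TMM factors except for the macrophage levels, the excesses over MycCaP, the folds against the floor, the summed eosinophil genes, Epcam, Krt15 and Krt18, which use gene counts alone. Gene lists, 44 in number, covered macrophage functions and markers of the other cell types that the tumour could hold. They were tested with limma's camera (preset correlation 0.01, run on edgeR's count object with its dispersions), again with an estimated correlation, and with fry, each adjusted over the 44 lists. A list that passes camera moves relative to other genes, while fry tests whether its genes move, on balance, in one direction. The lists, tests, alternatives and rule for named genes were chosen before the data were examined. The lists share some members, so their results are not independent.

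The named genes are Bmp4 and the genes of the sort markers, up to 12 genes in each direction with the largest fold change among genes that passed (none did), up to 4 members of each list with the smallest p and any member a sentence on the list needs, and, since fewer than 10 genes passed, the 10 with the smallest p. Rnase2a, Ear2, Igfbp5 and Krt15 fall outside the rule and were chosen after their values were seen. Some genes that the rule takes are not reported here. A gene with no count in a group is given a fold against 3 counts over that group. The macrophage level of a library is the median over the 15 pan-macrophage genes of the CPM relative to the MycCaP mean, with a 95% interval from 10000 bootstrap draws of the genes.

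The alternatives were DESeq2's size factors, library size alone, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, DESeq2's own test, limma-voom, a test against a fold change of 1.5, removal of marker genes of other cell types, and each library left out in turn. Scaling on the median of the pan-macrophage genes was added after the data were seen. The test was also run on simulated counts with 50 genes changed at each fold size. With the spread of all 4 libraries (13755 genes), it recovered 2% of genes changed 2-fold, 44% at 4-fold, 88% at 8-fold and 98% at 16-fold. With the spread of the MycCaP pair alone (13832 genes) it recovered 70%, 90%, 98% and 100%. The changed genes were drawn from those with a mean above 50 counts, and all genes varied independently. The shift that many genes shared between the 2 MycCaP-BMP4 libraries was absent, so these shares do not give the power of the real test. In the real fit Bmp4 did not pass at a log2 fold change of 11.59. Simulated libraries diluted to 0.25 and 0.75 of their macrophage level gave 0.249 and 0.747. There the added RNA held no pan-macrophage gene and counts varied by sampling only, so this checks the calculation and not the level in the real libraries. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.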

Results

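Messenger RNA was counted in macrophages sorted from tumours that grew under the skin of FVB mice. The tumours came from MycCaP cells, a mouse prostate cancer line derived from a prostate tumour of the same strain that carried a human MYC transgene, or from MycCaP cells that overexpress BMP4, a secreted bone morphogenetic protein that signals through SMAD transcription factors. Tumour-associated macrophages (TAMs) were taken from dissociated tumours as cells that carry CD45, CD11b and F4/80 at their surface and lack GR1. The cell type label is the same for all 4 samples, but the titles of the MycCaP-BMP4 samples name F4/80 and those of the MycCaP samples do not, so whether both groups were sorted with the same gate is open. Each group had 2 libraries. The MycCaP libraries held 24967143 and 24385036 counts in genes and the MycCaP-BMP4 libraries 24313328 and 23058263, for replicates 1 and 2 in that order, and values below are given in the same order. At this depth 3 counts, taken as the floor of detection, were worth 0.120 to 0.130 CPM (counts per 1000000 gene counts), which covers counting error only. The labels do not say whether the samples came from separate mice, so p-values measure only the spread between these samples, which may be technical.

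The comparison of the 2 groups addresses what BMP4 made by the tumour cells does to the macrophages in the tumour. The MycCaP-BMP4 libraries had lower normalised counts for genes of the interferon response, of antigen presentation and of T and NK cells, and higher counts for Bmp4, BMP target genes and tumour epithelial genes. All 34 interferon response genes tested lay lower in both MycCaP-BMP4 libraries than in both MycCaP libraries, with a median log2 fold change of -1.62, and 9 of 13 BMP target genes lay higher, with a median of 1.16. Genes that mark macrophages in general were also lower, to a median of 22.3% of the MycCaP mean in MycCaP-BMP4 replicate 1 (95% bootstrap interval over 15 genes, 19.7% to 29.9%) and 77.6% in replicate 2 (61.6% to 88.1%). Retnla, a secreted marker of alternatively activated macrophages, reached 4655 CPM in MycCaP-BMP4 replicate 2 against 189 CPM in replicate 1 and 159 and 78.9 CPM in the MycCaP libraries.

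No single gene passed the test at the 0.05 threshold: the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14075 genes, with 2680 genes at an unadjusted p under 0.05 (1729 higher and 951 lower in MycCaP-BMP4 TAMs) where chance gives 704. DESeq2 called 1385 genes (961 higher, 424 lower) and limma-voom 0, with 2743 genes at an unadjusted p under 0.05. When 1 MycCaP-BMP4 library was left out, the spread came from the MycCaP pair alone. The calls of such fits do not tell whether a difference repeats between MycCaP-BMP4 samples. The same limit holds for list calls below with 1 library left out. The log2 values of the MycCaP libraries correlated across genes with r = 0.974 and those of the MycCaP-BMP4 libraries with r = 0.928. The groups did not overlap for 4074 genes that were higher and 4184 that were lower in MycCaP-BMP4 TAMs, 58.7% of those tested, where chance gives 33.3%. When libraries were scaled on the macrophage markers in place of all genes, a choice made after the data were seen, the calls were 1028 higher and 23 lower, and the median log2 fold change of all genes moved from -0.03 to 1.65.

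**Figure D1:**
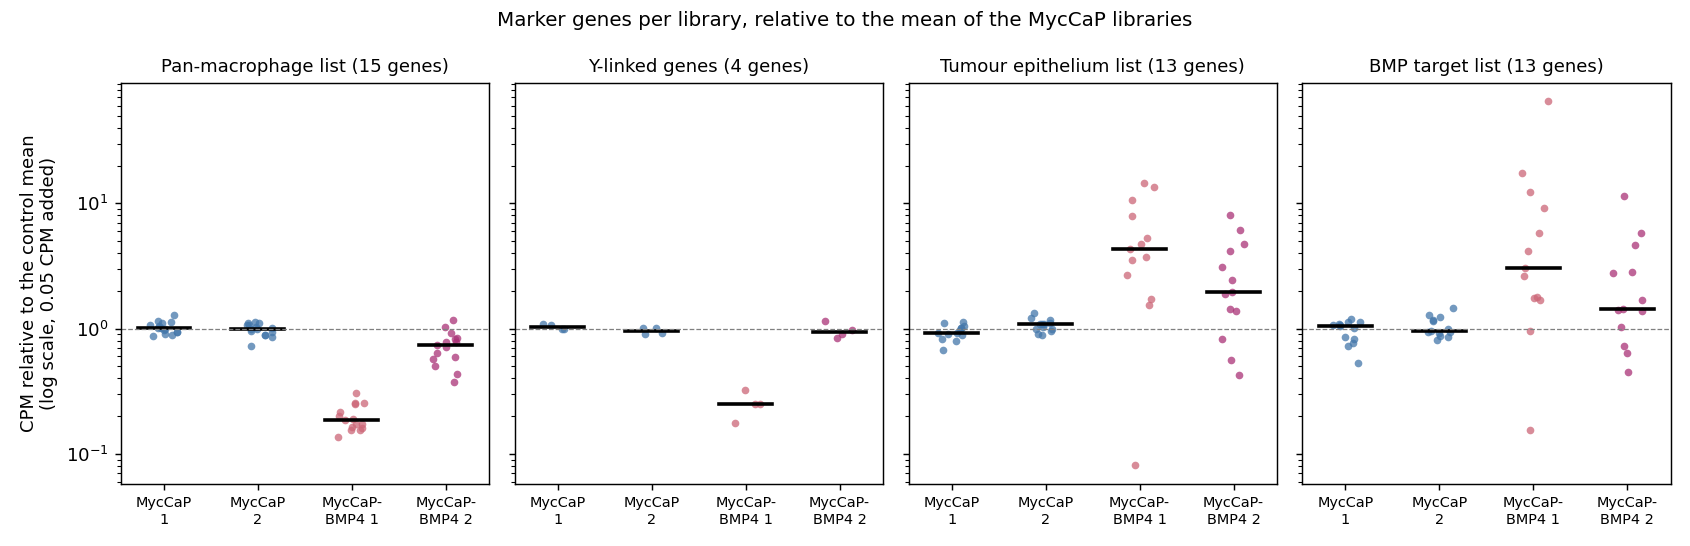
CPM of each gene relative to the mean of the 2 MycCaP libraries (log axis, 0.05 CPM added), for 15 pan-macrophage genes, 4 Y-linked genes, 13 tumour epithelium genes and 13 BMP target genes. Each point is a gene in 1 library and each bar the median of the list; the pan-macrophage genes sit lowest in MycCaP-BMP4 replicate 1, and most tumour epithelium and BMP target genes sit highest there.

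Bmp4 itself (ENSMUSG00000021835; chromosome 14, 46383520 to 46390669 on GRCm38, a protein-coding gene) stood at 0.175 and 0.0422 CPM (4 and 1 counts) in the MycCaP libraries and at 512 and 182 CPM in the MycCaP-BMP4 libraries. Its log2 fold change was 11.59 ± 0.95 (SE), with an adjusted p of 0.0729 by edgeR's quasi-likelihood test. Genes of the surface proteins selected by the sort were detected in all 4 libraries. Adgre1, which encodes F4/80, had 863 and 919 CPM in MycCaP TAMs and 146 and 638 CPM in MycCaP-BMP4 TAMs. Itgam (CD11b) had 714 and 876 CPM against 127 and 620 CPM, and Ptprc (CD45) had 650 and 689 CPM against 126 and 376 CPM. Ly6g, one of the GR1 antigens, had no count in any library, and of the Ly6c genes, related to the other, Ly6c2 had 4.77 and 4.39 CPM against 1.77 and 1.62 CPM and Ly6c1 had 3.67 and 6.24 CPM against 49.6 and 22.6 CPM. Ly6c1 was the 1 sort marker gene that passed when adjusted over that list alone (5 tested, median log2 fold change -1.19, camera adjusted p = 0.374). None of these genes passed the test across all genes.

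Of the 15 pan-macrophage genes, 12 lay lower in both MycCaP-BMP4 libraries and none higher (chance gives 16.7% in each direction). The median log2 fold change was -1.10, and the list was lower than other genes by limma's camera with a preset correlation (adjusted p = 8.34e-05) but not with an estimated correlation (adjusted p = 0.799 with an estimated correlation). The receptor gene Csf1r had 1835 and 2067 CPM in MycCaP TAMs and 423 and 1532 CPM in MycCaP-BMP4 TAMs, and the lysozyme gene Lyz2 had 10240 and 8193 CPM against 2360 and 8431 CPM. Scaled on the macrophage markers, the log2 fold changes of Csf1r and Lyz2 turned to 0.11 and 0.35, as that scaling holds the list near 0. The 4 tested Y-linked genes, which are not macrophage genes, had a median log2 difference from the MycCaP mean of -1.99 in MycCaP-BMP4 replicate 1 and -0.09 in replicate 2. Ddx3y, for example, had 137 and 117 CPM against 31.9 and 124 CPM, and its fold change also turned positive, to 0.37, under the macrophage scaling.

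Tumour epithelial genes were higher in the same libraries. Of 13 tested, 10 lay higher in both MycCaP-BMP4 libraries and 1 lower, with a median log2 fold change of 1.51, and camera called the list (adjusted p = 1.85e-05; adjusted p = 0.799 with an estimated correlation). No member passed across all genes and 6 passed when adjusted over the list alone, all higher. Cldn3, a tight junction gene, had 25.8 and 27.6 CPM in MycCaP TAMs and 359 and 126 CPM in MycCaP-BMP4 TAMs. The prostate homeobox gene Hoxb13 had 6.12 and 4.98 CPM against 23.9 and 7.73 CPM, and the keratin gene Krt19 had 1.44 and 1.31 CPM against 20.7 and 11.4 CPM. Not every epithelial marker did this: Cdh1, which encodes E-cadherin, had 5.16 and 4.05 CPM against 0.326 and 1.93 CPM, and Epcam and Krt18 stayed under 1 CPM in each library.

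The 10 genes with the smallest p, none of which passed, included Wif1, Agt, Orm3, Bmp4, Ucma, Itgbl1, Vit, Orm1 and Pdk4, with edgeR adjusted p from 0.0667 to 0.0729. Wif1, a secreted Wnt inhibitor (chromosome 10, 121033960 to 121100650), had 0.131 and 0.0844 CPM in MycCaP TAMs and 366 and 174 CPM in MycCaP-BMP4 TAMs, a log2 fold change of 11.23 ± 0.69 (SE). Orm1 and Orm3, which encode orosomucoid acute-phase proteins, had log2 fold changes of 5.56 ± 0.51 and 6.65 ± 0.54, and Pdk4, a kinase that restrains pyruvate dehydrogenase, had 4.60 ± 0.42. Vit had no count in MycCaP TAMs and 21.9 and 16.3 CPM in MycCaP-BMP4 TAMs. On gene counts alone, without TMM factors, it was at least 339-fold higher against a floor of 3 counts over the group. In the other direction, Agt, the angiotensin precursor gene (chromosome 8, 124556534 to 124569706), had 41.7 and 65.5 CPM in MycCaP TAMs and 0.362 and 0.176 CPM in MycCaP-BMP4 TAMs, a log2 fold change of -7.58 ± 0.52. Itgbl1 fitted at -7.83 ± 0.70. Ucma, a cartilage matrix gene, had 11.4 and 13.04 CPM against 0.0362 and 0 CPM.

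The state of the macrophages was compared with lists of alternative and classical activation genes. Alternative activation genes respond to IL-4 and related signals. Their median difference from the MycCaP mean was -1.97 in log2 in MycCaP-BMP4 replicate 1 and 0.08 in replicate 2. The pan-macrophage list was at -2.42 and -0.43. Relative to that list the alternative activation medians were similar, at 0.45 and 0.51, although single members differed between the replicates. Of 30 genes tested, 12 lay lower in both MycCaP-BMP4 libraries and 1, Retnla, lay higher. Retnla (chromosome 16, 48842551 to 48844461) had a mean of 119 ± 56.8 CPM (SD, n = 2) in MycCaP TAMs and 2422 ± 3158 CPM (SD, n = 2) in MycCaP-BMP4 TAMs, a difference smaller than the spread of the second group. Chil3, a chitinase-like gene, had 11.5 and 6.46 CPM against 8.25 and 215 CPM. The arginase gene Arg1 had 744 and 623 CPM against 81.3 and 1073 CPM, and the mannose receptor gene Mrc1 had 2312 and 2338 CPM against 416 and 2089 CPM. Il1r2, a decoy receptor gene for interleukin-1, was lower in both, at 19.4 and 22.99 CPM against 4.27 and 5.36 CPM, and was the 1 member that passed when adjusted over the list alone, with 0 across all genes.

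The alternative activation list had a median log2 fold change of -0.54 and a mean of -0.13, and camera called it lower than other genes (adjusted p = 0.0187; adjusted p = 0.799 with an estimated correlation). The direction rested on MycCaP-BMP4 replicate 1: without it the median was 0.07 and camera called the list higher (adjusted p = 0.00023; adjusted p = 0.689 with an estimated correlation). Scaled on the macrophage markers the median was 0.42, still below that of all genes (camera adjusted p = 0.00666, lower; adjusted p = 0.635 with an estimated correlation).

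Classical activation genes, which respond to interferon-gamma and bacterial products, were lower in both MycCaP-BMP4 libraries. Of 28 tested, 24 lay lower in both and none higher, with a median log2 fold change of -1.22, and camera called the list (adjusted p = 5.8e-09; adjusted p = 0.799 with an estimated correlation). No member passed the test, either across all genes or adjusted over the list alone. The nitric oxide synthase gene Nos2 had 8.44 and 9.92 CPM in MycCaP TAMs and 0.724 and 2.24 CPM in MycCaP-BMP4 TAMs. Cxcl9, a chemokine gene induced by interferon-gamma, had 46.0 and 61.1 CPM against 7.06 and 16.5 CPM, and Gbp2 had 175 and 178 CPM against 23.8 and 66.3 CPM. The median difference from the MycCaP mean was -2.44 in replicate 1 and -0.62 in replicate 2, beside -2.42 and -0.43 for the pan-macrophage list. Without MycCaP-BMP4 replicate 1 the list median was -0.64, and scaled on the macrophage markers it was -0.05.

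**Figure D2:**
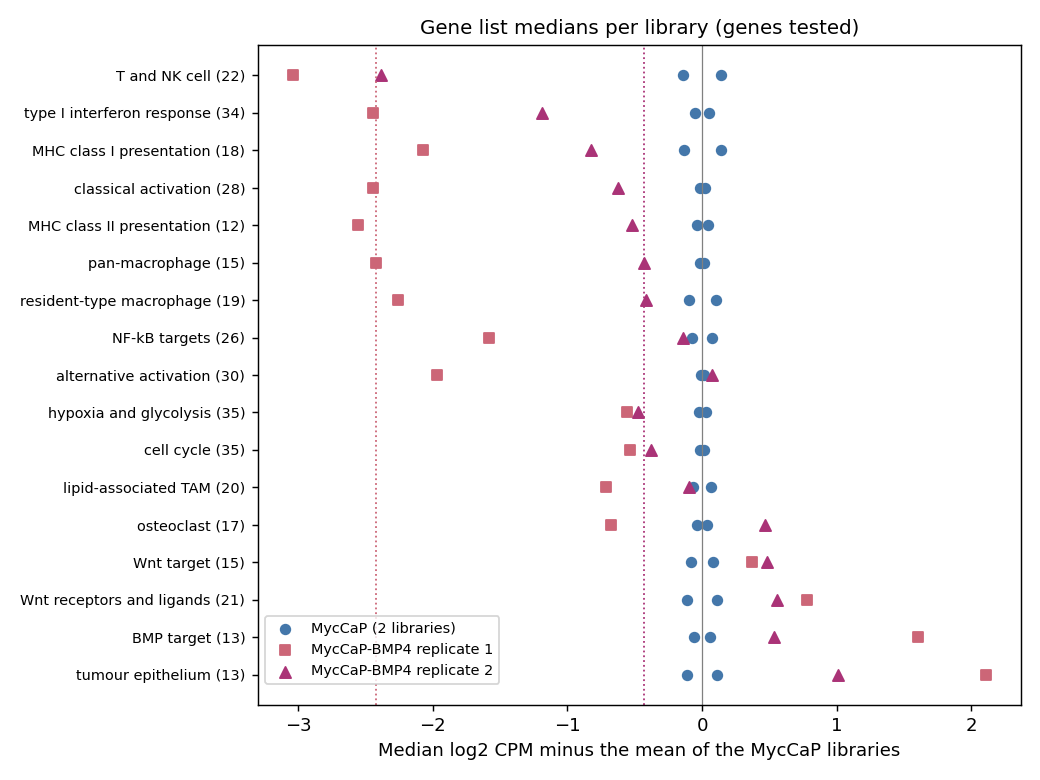
Median log2 CPM of 17 gene lists in each library, as the difference from the mean of the MycCaP libraries, with the number of genes tested in brackets. Dotted lines mark the pan-macrophage median in MycCaP-BMP4 replicate 1 (-2.42) and replicate 2 (-0.43). In replicate 2 the T and NK cell and interferon response lists lie furthest left of the second line. The MHC class I, classical activation, MHC class II, and hypoxia and glycolysis lists lie left of it too.

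All 34 tested genes of the type I interferon response lay lower in both MycCaP-BMP4 libraries, and 25 passed when adjusted over the list alone, with 0 across all genes. Camera called the list (adjusted p = 8.59e-20; adjusted p = 0.799 with an estimated correlation). Irf7, a transcription factor gene that amplifies interferon production, had 264 and 245 CPM in MycCaP TAMs and 35.0 and 74.8 CPM in MycCaP-BMP4 TAMs, and Ifi44 had 21.0 and 21.1 CPM against 2.06 and 3.38 CPM. The list median differed from the MycCaP mean by -2.44 in replicate 1 and by -1.19 in replicate 2, against -2.42 and -0.43 for the pan-macrophage list, and without MycCaP-BMP4 replicate 1 the median log2 fold change was -1.20. Scaled on the macrophage markers it was -0.32.

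Antigen presentation genes were lower as well. All 18 tested genes of MHC class I presentation lay lower in both MycCaP-BMP4 libraries, 7 passed when adjusted over the list alone and 0 across all genes, and the median log2 fold change was -1.34 (camera adjusted p = 1.92e-08; adjusted p = 0.799 with an estimated correlation). The peptide transporter gene Tap1 had 173 and 149 CPM against 22.8 and 57.6 CPM, and the immunoproteasome gene Psmb8 had 294 and 181 CPM against 34.1 and 84.3 CPM. Of 12 MHC class II genes, 10 lay lower and none passed, with a median of -1.21 (camera adjusted p = 0.000209; adjusted p = 0.799 with an estimated correlation). Genes of other cells that carry MHC class II were lower too: dendritic cell genes had a median of -1.24 (18 tested, 12 lower and 3 higher in both libraries; camera adjusted p = 0.0103; adjusted p = 0.799 with an estimated correlation) and B and plasma cell genes -1.22 (10 tested, 8 lower and 1 higher; camera adjusted p = 0.00216; adjusted p = 0.799 with an estimated correlation). Without MycCaP-BMP4 replicate 1 the dendritic cell list was not called (median -0.62). Scaled on the macrophage markers its median turned to 0.16, beside 1.65 for all genes. Camera still called the list lower under that scaling (adjusted p = 0.00018, or 0.685 with an estimated correlation). The B and plasma cell median in replicate 2 was -0.82. Adjusted over the list alone, 1 dendritic cell gene passed, higher, and 2 B and plasma cell genes, lower, with 0 across all genes. Ciita, the class II transactivator gene, had 17.4 and 21.1 CPM against 2.03 and 7.60 CPM. The class I and class II medians in replicate 2 were -0.83 and -0.52, beside -0.43 for the pan-macrophage list, and scaled on the macrophage markers the medians over both libraries were -0.04 and -0.14.

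T and NK cell genes, which the sort should exclude, were at low levels in MycCaP TAMs and lower in MycCaP-BMP4 TAMs. Of 22 tested, 21 lay lower in both libraries, and 17 passed when adjusted over the list alone, with 0 across all genes. The median log2 fold change was -2.72 (camera adjusted p = 3.36e-16; adjusted p = 0.702 with an estimated correlation), and the medians of -3.04 and -2.39 in the 2 MycCaP-BMP4 libraries were both below those of the pan-macrophage list. Scaled on the macrophage markers the median was -1.15. The granzyme gene Gzma had 7.13 and 4.98 CPM in MycCaP TAMs and 0.651 and 0.395 CPM in MycCaP-BMP4 TAMs, Cd8a had 3.85 and 2.74 CPM against 0.290 and 0.263 CPM, and the NK receptor gene Klrk1 had 17.5 and 20.8 CPM against 1.38 and 3.16 CPM.

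BMP target genes were higher in both MycCaP-BMP4 libraries and more so in replicate 1. Of 13 tested, 9 lay higher and 1 lower, and 5 passed when adjusted over the list alone, all higher, with 0 across all genes (camera adjusted p = 0.000322; adjusted p = 0.799 with an estimated correlation). Id1, an inhibitor of differentiation gene induced directly by BMP receptors, had 9.97 and 8.40 CPM in MycCaP TAMs and 160 and 52.9 CPM in MycCaP-BMP4 TAMs. The inhibitory SMAD gene Smad6 had 4.42 and 3.38 CPM against 48.6 and 18.3 CPM, Smad9 had 3.24 and 4.60 CPM against 36.0 and 11.2 CPM, and Atoh8 had 0.0874 and 0.169 CPM against 11.6 and 1.98 CPM. The list median was 1.61 in replicate 1 and 0.54 in replicate 2, the order seen for the tumour epithelium list, at 2.11 and 1.01. Without MycCaP-BMP4 replicate 1 the median was 0.52, and scaled on the macrophage markers it was 3.14, where the tumour epithelium list had 3.59 and all genes 1.65.

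Wnt target genes were higher by less. Of 15 tested, 9 lay higher and 3 lower, the median log2 fold change was 0.58, and camera called the list (adjusted p = 0.0164; adjusted p = 0.702 with an estimated correlation). The call did not hold without MycCaP replicate 2, without MycCaP-BMP4 replicate 1, or with no filter on low counts (median 0.20, camera adjusted p = 0.208). Scaled on the macrophage markers the median was 2.01, beside 1.65 for all genes (camera adjusted p = 0.0375, or 0.829 with an estimated correlation). Fosl1, a subunit gene of the AP-1 transcription factor, was the 1 member that passed when adjusted over the list alone, with 0 across all genes, at 4.98 and 4.30 CPM against 79.3 and 41.1 CPM. Myc, as annotated in the mouse, had 59.4 and 87.9 CPM against 408 and 163 CPM, and Apcdd1, a Wnt inhibitor gene, had 1.62 and 3.76 CPM against 24.1 and 9.04 CPM. Whether reads of the human MYC transgene of the tumour line were counted at mouse Myc was not tested. Among 21 Wnt ligand, receptor and inhibitor genes, 10 lay higher and 4 lower, and 6 passed when adjusted over the list alone, all higher, with 0 across all genes (median 0.44; camera adjusted p = 0.000322; adjusted p = 0.702 with an estimated correlation). Wnt4 had 22.4 and 29.7 CPM against 212 and 81.7 CPM, Wnt7b had 2.75 and 5.32 CPM against 46.6 and 25.5 CPM, and Wnt5a had 2.06 and 2.83 CPM against 15.6 and 7.81 CPM. Their excess over MycCaP was 3.86, 2.31 and 2.86 times as large in replicate 1 as in replicate 2. Fosl1, Myc and Apcdd1 had 2.37, 4.32 and 3.89, beside 3.24 for Bmp4. List medians in replicates 1 and 2 were closer, at 0.374 and 0.485 for Wnt targets and 0.776 and 0.553 for the ligand, receptor and inhibitor genes. Wnt genes of the macrophages were not separated from those of tumour cells.

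**Figure D3:**
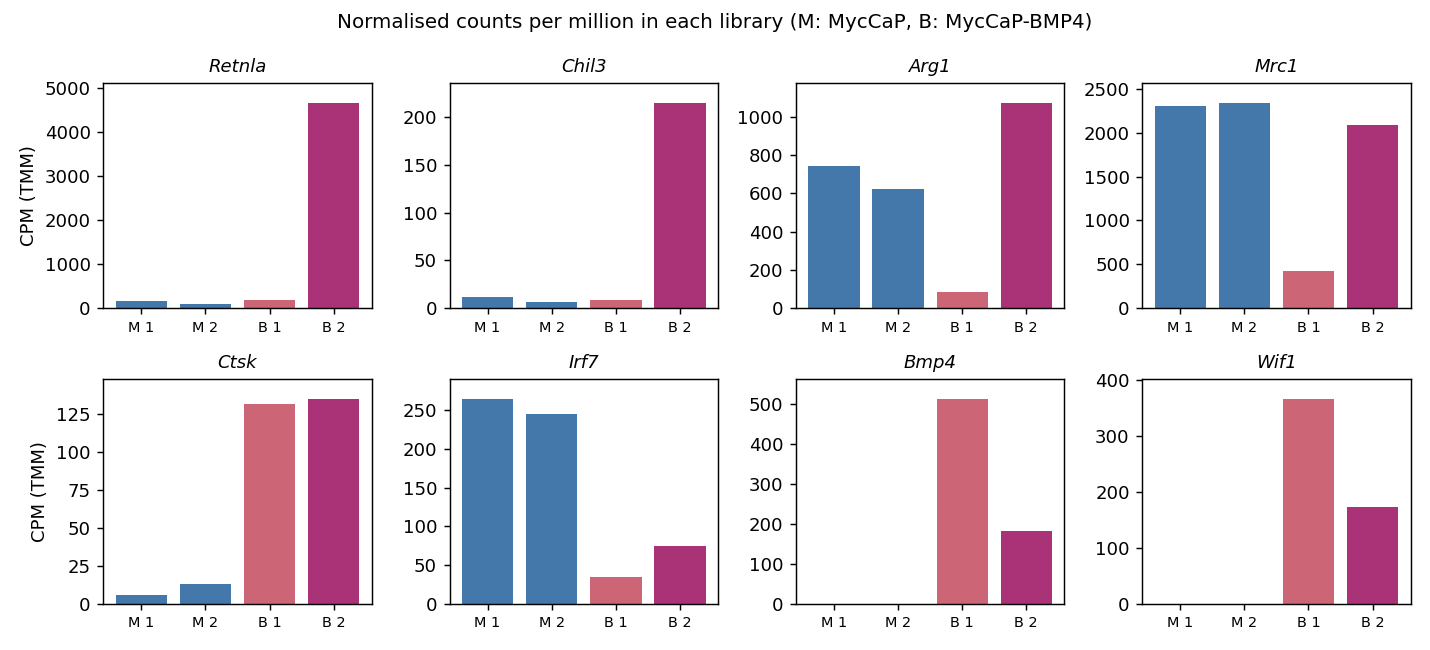
TMM-normalised CPM of Retnla, Chil3, Arg1, Mrc1, Ctsk, Irf7, Bmp4 and Wif1, with 1 bar per library and linear axes that start at 0. Retnla and Chil3 stand high in MycCaP-BMP4 replicate 2 alone (4655 and 215 CPM), while Ctsk is at similar levels in both MycCaP-BMP4 libraries (132 and 135 CPM).

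The study concerns bone-forming prostate tumours, and genes of osteoclasts, osteoblasts and cartilage were also examined. The osteoclast list was not called (17 genes, median log2 fold change 0.03, camera adjusted p = 0.211), but 3 members passed when adjusted over the list alone, all higher, with 0 across all genes. Ctsk, which encodes the bone-degrading protease cathepsin K, had 5.60 and 13.3 CPM in MycCaP TAMs and 132 and 135 CPM in MycCaP-BMP4 TAMs, a log2 fold change of 3.82 ± 0.48 (SE; edgeR adjusted p = 0.0903). The integrin gene Itgb3 had 9.79 and 11.3 CPM against 114 and 58.2 CPM. Its excess over MycCaP was 2.53 times as large in replicate 1 as in replicate 2, beside 3.24 for Bmp4 and 1.14 for Ctsk. Without MycCaP-BMP4 replicate 1 the osteoclast list had a median of 0.43 and was called higher (camera adjusted p = 2.68e-06; adjusted p = 0.689 with an estimated correlation).

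The osteoblast and bone matrix list was not called (12 genes, median 0.21, camera adjusted p = 0.0683), and 4 members passed when adjusted over the list alone, 3 of them higher. The bone sialoprotein gene Ibsp had no count in MycCaP TAMs and 1.77 and 1.93 CPM in MycCaP-BMP4 TAMs. On gene counts alone, without TMM factors, Ibsp was at least 32.3-fold higher against the floor over the group. Alpl, the bone alkaline phosphatase gene, had 0.0437 and 0.380 CPM against 2.39 and 2.85 CPM. The cartilage list was called higher by camera (10 genes, 4 higher in both libraries, 1 lower and 5 overlapping, median 1.16, adjusted p = 0.00299; adjusted p = 0.702 with an estimated correlation) and by fry (adjusted p = 0.0387), and 4 members passed when adjusted over the list alone, all higher, with 0 across all genes. Its median was the same with the 3 members at 0 in MycCaP TAMs set to their bounds. The bounds also lie above the median, so this does not bear on the calls. Sox9, the master transcription factor gene of cartilage, had 11.2 and 19.3 CPM against 128 and 65.5 CPM. Its excess over MycCaP was 2.61 times as large in replicate 1 as in replicate 2, beside 3.24 for Bmp4 and 0.28 for Col2a1. The collagen gene Col2a1, at 0.941 and 3.86 CPM, was at least 39.6-fold higher on gene counts alone, whereas Ucma, which is not in the list, was lower.

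Of the 44 lists, camera called 24 with the preset correlation, 19 lower and 5 higher, and 0 with an estimated correlation, where the adjusted p of those 24 ranged from 0.702 to 0.799. In simulated counts with a planted 4-fold change of 30 genes, camera with the estimated correlation gave an adjusted p of 0.102 for the planted list. With the preset correlation it gave 1.04e-73 and also called 1 of the 44 other lists. The simulated genes varied independently, whereas the estimated correlation in the real lists was, for example, 0.912 for the interferon response and -0.005 for Wnt targets. The preset result there thus does not bear on the 24 real calls. The estimated correlation missed even the planted change, so a list it does not call may still have moved.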

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

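All tests of explanations in this part were chosen after the results were seen. Reads outside annotated genes stood out because they were more frequent in both MycCaP-BMP4 libraries (mean 6.02% of counted reads) than in either MycCaP library, and reads that aligned to several places for the same reason (mean 9.97%).

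Macrophage markers were low, and Bmp4 and tumour epithelial markers high, in the MycCaP-BMP4 libraries, most of all in replicate 1. Lower depth is argued against, since replicate 1 had 0.985 of the mean gene counts of the MycCaP libraries, and lower expression within its macrophages as the whole cause is argued against by Y-linked genes, which it would leave in place and which were at -1.99 in log2 there (tumour cell RNA would lower them only if the line carries little Y-linked RNA, which was not tested). RNA from tumour cells in the sorted samples may account for it. Bmp4, which the tumour cells overexpress, had 4 and 1 counts in the MycCaP libraries and 14136 and 4138 in the MycCaP-BMP4 libraries. That goes with tumour cell RNA in these libraries but gives no share of it, and Bmp4 made by the macrophages was not tested. The ratio tested cannot decide whether tumour cell RNA accounts for the whole pattern. The summed excess of all 13 tested tumour epithelial genes over MycCaP was 5.03 times as large in replicate 1 as in replicate 2 (a sum chosen after the results were seen). The median was 3.12 over the 10 picked as higher in both libraries. The sum lay within the interval of 2.02 to 5.87 around the 3.47 predicted from the macrophage signal missing from each library. That prediction takes the loss in replicate 2 as dilution, although Y-linked genes were at -0.09 there. A ratio above 1 was also common, in 300 of 322 abundant genes picked as higher in both libraries and at least 2-fold higher in replicate 2. Of the 13 epithelial genes, 11 were at 1 CPM or more in MycCaP TAMs too. Cdh1 was lower in both MycCaP-BMP4 libraries, Epcam and Krt18 were near 0, and the sort on CD45, CD11b and F4/80 should remove tumour cells. Krt15, a keratin gene chosen after its values were seen, was higher. It had 39.0 and 46.05 CPM in MycCaP TAMs and 1067 and 404 CPM in MycCaP-BMP4 TAMs. What lowered the macrophage markers in replicate 2, where Y-linked genes were at -0.09, was not tested, BMP target genes induced in the macrophages were not separated from those of tumour cells, and a sort gate that differed between the groups stays open as untested.

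The interferon response list had a median of -1.19 in log2 in MycCaP-BMP4 replicate 2, against -0.43 for the pan-macrophage list, and -2.44 against -2.42 in replicate 1, and no explanation for this was tested.

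Retnla, Chil3, Rnase2a, Ear2 and Alox15 were high in MycCaP-BMP4 replicate 2. The median excess over MycCaP in replicate 1 was 0.00478 of that in replicate 2, unlike the tumour epithelial genes. The 5 genes were grouped for being high in replicate 2, so this ratio restates their pattern and is no separate test of tumour cell RNA. Eosinophils in the sort stay open: the summed CPM of 6 eosinophil genes was 1.07 times the MycCaP mean in replicate 2 (Ccr3 at 6.76 and Siglecf at 1.45 CPM), but 2 of the 6 alone reached 1 CPM in MycCaP TAMs, and eosinophils also express Rnase2a, Ear2 and Alox15. The wider list with mast cell and basophil genes had a median of 2.00 in log2 in replicate 2. Its 4 members with the smallest p, Hdc, Cpa3, Tpsab1 and Cma1, are mast cell genes, so that median does not speak for eosinophils. A macrophage state shared by both MycCaP-BMP4 tumours stays open too, since relative to the macrophage markers the median of the 5 genes was 5.01 times the MycCaP level in replicate 1, where a gene at its MycCaP level would have 4.49. A difference between single mice is equally open.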

How the results depend on the processing

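The scaling on macrophage markers was added after the data were seen, and the other settings were planned. The edgeR count of 0 changed genes held with DESeq2's size factors, a filter of 1 CPM in 2 libraries, a test against a fold change of 1.5, limma-voom, and removal of markers of other cell types. It became 65 (47 higher, 18 lower) with library size alone, 1109 (784, 325) with no filter on low counts, 1385 (961, 424) by DESeq2, and 1051 (1028, 23) when scaled on the macrophage markers. With 1 library left out, the remaining one is assumed to vary like the other group: the count ranged from 0 to 5753, from 0 to 2753 higher and from 0 to 3000 lower. Genes were called only where the closer MycCaP pair set it, and such calls do not tell whether a difference repeats. With the replicate block the edgeR count of changed genes was 2 (2 higher, 0 lower), Wif1 and Bmp4. Replicate differences correlated across genes with r = -0.12 between the groups, and the labels do not say whether equal numbers mark a shared mouse, day or batch. DESeq2 and the fit without MycCaP-BMP4 replicate 1 shared 823 called genes.

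The lists called numbered 24, and 0 with an estimated correlation and 1 by fry. With these the alternative activation list (-0.54) had adjusted p of 0.799 and 0.648, the classical (-1.22) 0.799 and 0.425, the Wnt target (0.58) 0.702 and 0.35, and the BMP target (1.16) 0.799 and 0.425. The alternative activation median ranged from -1.96 to 0.073 with 1 library left out and was 0.42 when scaled on the macrophage markers. The Wnt target median was 0.20 with no filter (adjusted p = 0.208) and ranged from 0.37 to 0.54 with 1 library left out. The classical and BMP target lists kept their direction under the other settings, from -2.42 to -0.64 and from 0.52 to 1.62 with 1 library left out. With all 4 libraries they also kept their camera call, but camera compares a list with other genes, so a change of scaling moves it little. Scaled on the macrophage markers their medians were -0.05 and 3.14, beside 1.65 for all genes and -0.08 for the pan-macrophage list. The classical list was thus near the macrophage markers under that scaling.

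Scaled on the macrophage markers, log2 fold changes turned positive for Ly6c2 (0.29), Csf1r (0.11), Lyz2 (0.35), Arg1 (0.43), Mrc1 (0.08), Slc2a1 (0.29), Pdk1 (0.75), Ccr3 (0.23), Siglecf (0.23) and Ddx3y (0.37). The median of all genes was 1.65 under that scaling. With 1 library left out, Arg1 ranged from -3.04 to 0.65, Siglecf from -3.25 to 0.40, Chil3 from -0.094 to 4.58, Ear2 from -0.51 to 3.71, Alox15 from -0.30 to 3.87, Cd163 from -0.98 to 2.35 and Lyve1 from -0.85 to 1.64.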

Other observations

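The scaling on macrophage markers, the ratios of excesses and Igfbp5 were chosen after the results were seen, and the list tests were planned. Several further groups differed between the libraries. Genes of hypoxia and glycolysis were lower in MycCaP-BMP4 TAMs (35 tested, 23 lower in both libraries and none higher, median log2 fold change -0.46, camera adjusted p = 0.000209; adjusted p = 0.702 with an estimated correlation), with 0 members called across all genes or adjusted over the list alone. The glucose transporter gene Slc2a1 had 277 and 226 CPM against 87.1 and 122 CPM, the prolyl hydroxylase gene Egln3 40.5 and 34.2 CPM against 2.93 and 11.2 CPM, and Pdk1 66.3 and 63.3 CPM against 34.2 and 31.4 CPM, although Slc2a1 and Pdk1 turned positive when scaled on the macrophage markers (0.29 and 0.75). Cell cycle genes were also lower (35 tested, 28 lower and 2 higher, median -0.49, camera adjusted p = 0.000712; adjusted p = 0.702 with an estimated correlation). Unlike the macrophage markers, both lists had similar medians in the MycCaP-BMP4 libraries, at -0.56 and -0.48 for hypoxia and glycolysis and at -0.53 and -0.38 for the cell cycle. Scaled on the macrophage markers, their medians turned to 1.21 and 1.18, beside 1.65 for all genes, and camera still called hypoxia and glycolysis lower (adjusted p = 0.0113; adjusted p = 0.829 with an estimated correlation) but not the cell cycle (adjusted p = 0.319).

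Monocyte genes moved in both directions, with 11 of 17 members called when adjusted over the list alone (8 lower, 3 higher, and 0 across all genes). The list median was -0.77 (camera adjusted p = 0.000494, or 0.702 with an estimated correlation), and the list was not called without MycCaP-BMP4 replicate 1 (median -0.71). Scaled on the macrophage markers the median was 0.38, beside 1.65 for all genes. Camera still called the list lower there (adjusted p = 0.00274, or 0.682 with an estimated correlation). Ace, an enzyme gene of patrolling monocytes, had 22.6 and 24.3 CPM against 2.50 and 3.95 CPM, and Ms4a4c had 64.0 and 68.6 CPM against 8.79 and 15.1 CPM. Among 25 matrix protease and inhibitor genes, 5 were called lower and 2 higher when adjusted over the list alone (0 across all genes). The median was -0.57 (camera adjusted p = 0.0103, or 0.799 with an estimated correlation), and that list was not called without MycCaP-BMP4 replicate 1 either (median -0.18). Scaled on the macrophage markers its median was 0.62, beside 1.65 for all genes. Camera again called it lower (adjusted p = 6e-05, or 0.635 with an estimated correlation). The collagenase gene Mmp13 had 249 and 293 CPM against 25.7 and 50.7 CPM, while the inhibitor gene Timp1 had 11.4 and 11.1 CPM against 28.3 and 45.2 CPM. Of the iron and heme genes (19 tested, camera adjusted p = 0.163), the iron exporter gene Slc40a1 had 265 and 286 CPM against 39.2 and 64.3 CPM, and the transferrin receptor gene Tfrc had 76.5 and 86.7 CPM against 221 and 405 CPM. These were the 2 iron genes called when adjusted over the list alone, and scaled on the macrophage markers they were at -0.94 and 3.36 (edgeR adjusted p = 0.497 and 0.0377). Gpnmb, of the lipid-associated macrophage list (20 genes, camera adjusted p = 0.637), had 48.4 and 57.0 CPM against 541 and 199 CPM. Its excess over MycCaP was 3.85 times as large in replicate 1 as in replicate 2, beside 3.24 for Bmp4.

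Ctsk differed from most genes that were high in the MycCaP-BMP4 libraries, as its excess over MycCaP TAMs was 1.14 times as large in replicate 1 as in replicate 2, where the median of 322 abundant genes, picked as higher in both libraries and at least 2-fold higher in replicate 2, was 2.97 (quartiles 2.24 and 3.71) and Bmp4 had 3.24. Igfbp5 had 351 and 690 CPM in MycCaP TAMs and 6.33 and 1.76 CPM in MycCaP-BMP4 TAMs, with a log2 fold change of -7.00 ± 0.84 (SE; edgeR adjusted p = 0.0903). Of the alternative activation genes beside Retnla, Chil3 and Alox15, Cd163 had 61.3 and 53.6 CPM against 28.6 and 293 CPM, and Lyve1 had 120 and 97.3 CPM against 59.2 and 340 CPM, and both turned negative without MycCaP-BMP4 replicate 2 (-0.98 and -0.85). Fibroblast genes were not called (20 tested, median -0.29, or 1.24 scaled on the macrophage markers, camera adjusted p = 0.78), nor were ribosomal protein genes (43 tested, median 0.19, camera adjusted p = 0.416). Mast cell, basophil and eosinophil genes were not called with all libraries (9 tested, 6 higher in both MycCaP-BMP4 libraries and 2 lower, median 1.45, camera adjusted p = 0.102). The 4 members with the smallest p were the mast cell genes Hdc, Cpa3, Tpsab1 and Cma1, all higher in both. Without MycCaP-BMP4 replicate 1 the list median was 1.80.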
